A study of Mus musculus with 20 samples.

How the data were processed

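RNA immunoprecipitation followed by sequencing (RIP-seq) was carried out with an antibody against CPEB4 on wild-type (WT) and Cpeb4 knockout (KO) mouse CD8 T cells that had been activated for 48 h with 1 μg/ml anti-CD3, 1 μg/ml anti-CD28 and 20 ng/ml IL-2, per the labels' protocols. Input RNA was purified over poly(A) beads and amplified for 12 PCR cycles, whereas the immunoprecipitate (IP) was not poly(A) purified and was amplified for 7 cycles, per the labels' protocols. The 20 samples were sequencing runs of 12 libraries. They carry the names D1, D3 and RIP8, each with 1 library of WT input, KO input, WT IP and KO IP, and these 3 sets are called experiments here. The titles give D1 and D3 a shared code, MFA129, which RIP8 lacks, so D1 and D3 may be parts of 1 experiment. A second run existed for 8 of the libraries, and batch 2 held a run of all 12. The labels did not say whether the experiments came from separate animals, so p-values measure only the spread between these samples, which may be technical.

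The deposited table held raw read counts per 3′ UTR, with 20586 rows and 1 column per run, and the authors did not pool runs in it. The mm10 genome build, Bowtie 1.2.3, Bowtie2 2.2.2, R 3.5.1 and featureCounts are named per the submitters' processing notes. The version of featureCounts, the roles of both aligners, the annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here. Every column was assigned to its sample by its name, and 0 columns were left without a sample. Rows are named in the file by an Ensembl transcript and a UTR start position, without chromosome or gene symbol.

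Gene symbols were therefore assigned here by position from the RefSeq gene table of GRCm38, the same build. The UTR start equalled the start of a RefSeq gene in 3828 rows, against 6 rows after all positions had been shifted by 1000000 bases. These matches showed that the rows run through the chromosomes in turn, with 3823 of the matches on the chromosome of their own stretch of rows, which gave each row its chromosome. A symbol was taken where the UTR start was the start of a single gene or lay inside a single protein-coding gene of that chromosome, which held for 17708 rows. Of these, 16103 symbols stood in falling alphabetical order within their chromosome, the order the rows followed, and the other symbols were discarded. UTRs shared by overlapping or near-identical genes stayed unnamed or uncertain, and ribosomal protein, histone and Eno1b counts can include reads of related genes.

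The rows were checked before any test. Rows that share a UTR start should hold equal counts where they hold the same interval, and 227 start positions were shared by several rows. In the first 9 columns, 89 of 168 neighbouring rows with a shared start and over 20 summed counts held identical values in all 9 columns. In the last 11 columns, 0 of 147 did. The rank correlation over all rows between a column of the first set and a column of the second lay between −0.0131 and −0.00164 in all 99 pairs. Within the first 9 columns it was 0.411 or more, but over rows with at least 20 summed counts and without the leading row. The values of the last 11 columns thus do not belong to the row names beside them. No level or fold of a named gene was taken from these columns. They enter totals, the share of the leading row, comparisons among themselves that need no row name and, under the row names as they stand, only counts of rows of gene families and the added fit of all 12 libraries.

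The tests had been fixed before the data were examined, for all 12 libraries. Because the rows did not match, they were run on the 9 columns in register, which the names assign to 6 libraries: WT input D1, WT input RIP8 with 2 runs, KO input D1, KO input RIP8 with its batch 2 run, WT IP D1 with 2 runs and KO IP D1 with 2 runs. Runs of a library were summed. edgeR 4.0.16 was used in R 4.3.3 with TMM factors, filterByExpr by group at its minimum count of 10, a group means model without covariates and the quasi-likelihood F test, and p-values were adjusted by Benjamini-Hochberg over the 11241 rows that passed the filter, 8955 of them with a symbol. The fit had 2 residual degrees of freedom, both from the inputs, so each lone IP library was assumed to vary like the inputs, and its common dispersion was 0.288. The threshold was an adjusted p of 0.05. Each edgeR SE was taken as the absolute log2 fold change over the square root of the F statistic. It thus restates the test and is no separate estimate of error. Gene lists, 25 of them, were tested with limma 3.58.1 camera at a preset correlation of 0.01, with an estimated correlation and with fry, where at least 3 members were tested.

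Named genes followed a fixed rule. Cpeb4 came first. Each comparison then named the genes with the smallest p among those past the threshold, and where too few passed, up to 5 higher and up to 5 lower genes with the smallest p, said not to have passed. Lists added up to 4 members with the smallest p in the knockout-controlled comparison. Symbols ending in Rik and predicted Gm genes were skipped. Alternatives were the batch 2 runs alone, DESeq2 1.42.0, limma voom, RLE factors, no factors, no filter, a filter at a minimum count of 50, the experiment as a replicate block, fits on the compared groups alone and each library left out. Added after seeing the data were the other run of each library with 2 runs, all 12 libraries as the table stands, a fit without the leading UTR, and the lists with each library left out. The test of CPE motifs in 3′ UTRs against the binding comparison needed genome sequence and was not run.

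The scripts were tested on simulated data. Counts for 11241 rows were drawn from the means and library sizes of the 6 libraries with 200 rows changed in the WT IP library. At the dispersion of these data, 0 of 67 rows changed 2-fold, 0 of 67 changed 4-fold and 0 of 66 changed 8-fold were recovered in the knockout-controlled comparison. At a dispersion of 0.01, 10 of 67, 62 of 67 and 66 of 66 were recovered, with 8 false calls. Shares of counts carry 95% Wilson intervals and counts carry 95% exact Poisson intervals. PCR reads without molecular identifiers are not independent molecules, so these intervals cover counting error only. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.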

Results

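CPEB4 is an RNA-binding protein that recognises cytoplasmic polyadenylation elements in 3′ UTRs. The study asked which mRNAs it binds in activated CD8 T cells, by immunoprecipitating it from WT cells and from KO cells that lack it. The groups were WT input, KO input, WT IP and KO IP, with 3 libraries each. Total 3′ UTR counts ran from 364113 to 5612280 per run and from 364113 to 6530901 per library. The values below are given for the library or run labelled with each name, since the counts contradict some of the names, as described next.

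The RNA in the 9 runs in register was that of activated CD8 T cells. Cd8a and Cd8b1, which encode the CD8 coreceptor, had 2872 and 2591 counts in the run labelled WT IP D1 batch 3 and 5044 and 2271 in the run labelled WT input RIP8 batch 2. Il2ra, the high-affinity IL-2 receptor chain, reached 5510 counts, and Gzmb, a cytotoxic granule protease, reached 17941 counts in the latter run. The haemoglobin gene Hba-a1 had at most 1 count in any of these runs. Summed over 14 named B cell markers, the level lay between 41.1 and 155 CPM (counts scaled to a run total of 1000000), against 1239 to 5441 CPM for 7 CD8 T cell markers. That CD8 T cell list also holds Thy1, Cd3e and Cd3g, which T cells in general express, so its sum does not set CD8 apart from CD4 T cells. With the Lars2 UTR taken out of the totals the ranges of the B cell and CD8 T cell lists were 63.0 to 159 and 2347 to 5570 CPM. The myeloid list of 20 markers summed to between 16.4 and 108 CPM and the NK cell list of 10 to between 6.62 and 34.1 CPM. The CD4 T cell list of 9 summed to between 58.3 and 121 CPM, the stromal list of 14 to between 15.4 and 74.9 CPM and the erythroid and platelet list of 10 to at most 8.24 CPM.

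**Figure D1:**
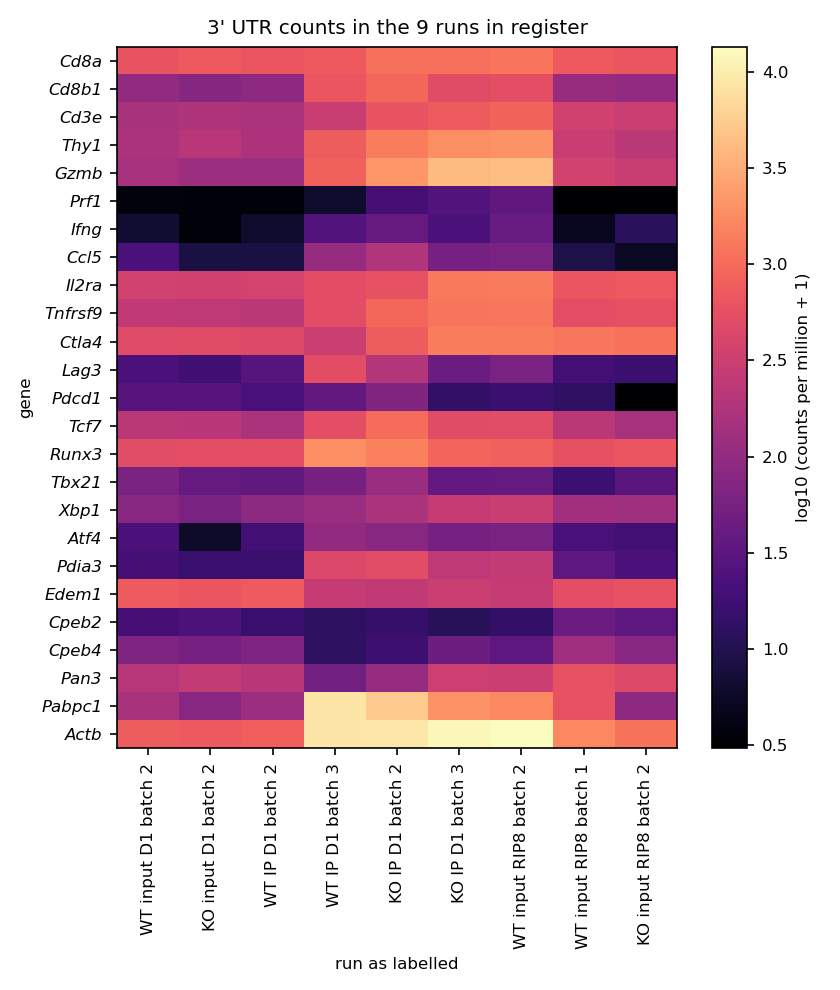
Levels of 25 genes of the fixed lists (rows) in the 9 runs whose rows match the row names (columns, as labelled), as log10 of CPM plus 1, without error bars. Cd8a stays high in all 9 runs, while Gzmb falls between 119 CPM in the run labelled WT IP D1 batch 2 and 4289 CPM in the run labelled WT input RIP8 batch 2.

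A single UTR took up much of some runs. It was the row of ENSMUST00000038863 starting at position 123461679 on chromosome 9 (mm10), which lies in Lars2, the gene of the mitochondrial leucyl-tRNA synthetase. Whether the reads in this row come from Lars2 mRNA was not tested, and the treatment of reads with several matches is not given. The row held 47.2% of the counts in the run labelled WT input D1 (95% Wilson interval 47.1 to 47.4%), 50.1% in KO input D1 and 48.6% in WT IP D1 batch 2. It held 34.8% in WT input RIP8 batch 1 and 37.0% in KO input RIP8 batch 2. In the other runs in register it held 1.16% in WT IP D1 batch 3, 2.23% in KO IP D1 batch 2, 5.40% in KO IP D1 batch 3 and 2.32% in WT input RIP8 batch 2. In the out-of-register runs, the leading row, which has no usable name, held between 2.32% in WT input D3 and 88.2% in KO IP D3 batch 3. The labels did not split the shares, with 1.34 to 88.2% over the 12 IP runs and 2.32 to 50.1% over the 8 input runs. The runs above every input run were all labelled IP: KO IP D3 batch 3, WT IP RIP8 batch 1 (85.3%) and KO IP RIP8 batch 2 (84.1%).

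**Figure D2:**
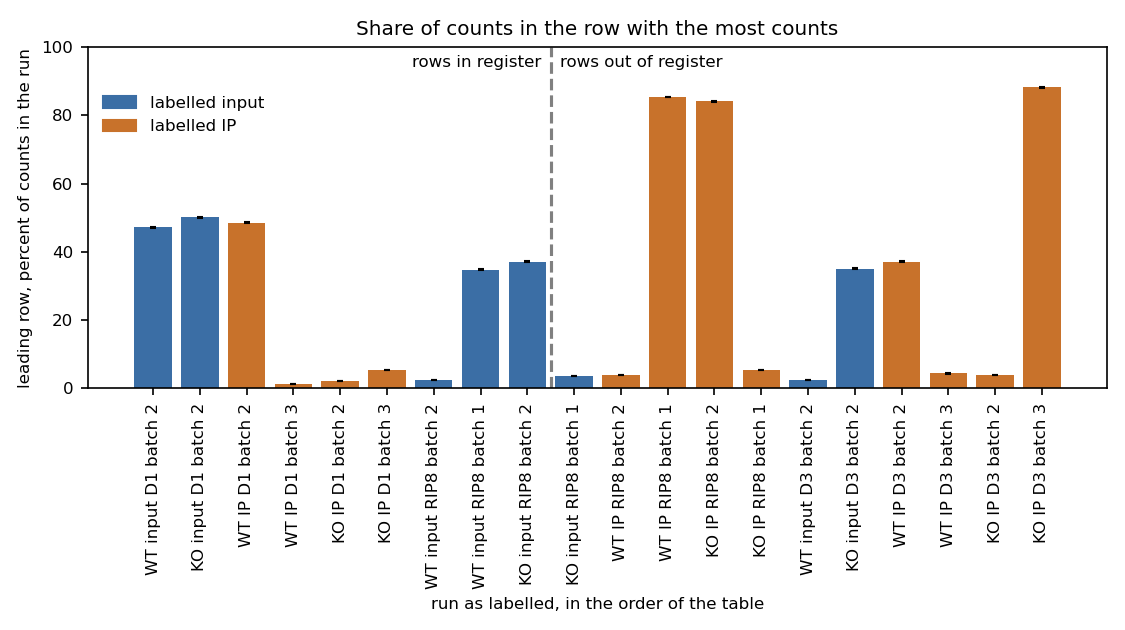
Percent of counts in the row with the most counts (bars, with 95% Wilson intervals, which are narrower than the lines can show) for each of the 20 runs, in the order of the table and coloured by the labelled input or IP. Values range from 1.34% to 88.2%, and both colours appear among the high and the low bars, while all bars above 50.1% are IP.

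Runs named for one library differed by more than sampling noise. In the first 9 columns, Pabpc1, the cytoplasmic poly(A)-binding protein, had 122 CPM in the run labelled WT IP D1 batch 2 and 8620 CPM in batch 3 of the same library. Gzmb had 119 CPM in batch 2 and 847 CPM in batch 3. The chi-square per degree of freedom between these runs, over rows with at least 20 summed counts and without the leading row, was 58.7. It was 35.0 between the runs named KO IP D1 and 31.7 between those named WT input RIP8. After thinning to 50000 counts these ratios were 7.62, 2.04 and 4.30. The rank correlations, over the same rows as the unthinned ratios, were 0.429, 0.914 and 0.706. By both measures after thinning and by rank, the runs named KO IP D1 were the most alike of these. In contrast, the runs labelled WT input D1, KO input D1 and WT IP D1 batch 2, which belong to 3 groups, had ratios of 1.05, 1.09 and 1.12 between them, close to the value of 1 that sampling noise alone gives. The run labelled KO IP D1 batch 3 had a ratio of 3.09 to WT input RIP8 batch 2, and WT input RIP8 batch 1 one of 1.39 to KO input RIP8 batch 2. Of 84 pairs of runs named for different libraries, 30 had a lower ratio than the lowest of the 7 pairs named for one library (7.21). No run was relabelled, and no direction below can be read as that of a genotype or of an IP beyond what the names say.

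**Figure D3:**
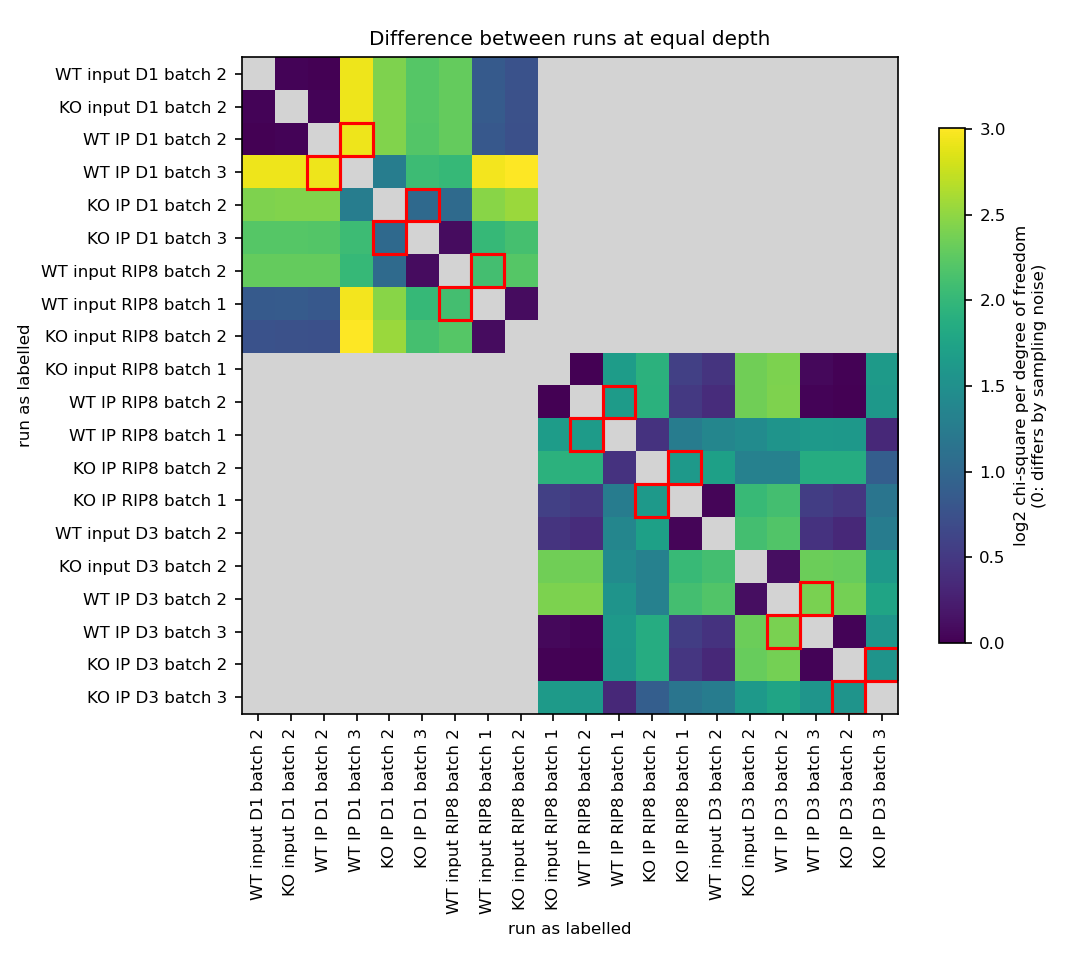
Difference between each pair of runs (axes, as labelled), as log2 of the chi-square per degree of freedom after thinning each run to 50000 counts without its leading row. Dark cells near 0 differ by sampling noise, grey cells are pairs with unlike row order, and red frames mark runs named for one library, which lie between 2.04 and 7.62 before the log, while some pairs of other names lie near 1.

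Cpeb4 itself was counted at the UTR starting at position 31931533 on chromosome 11 (mm10). Its level was 65.9 CPM (24 counts, 95% Poisson interval 42.2 to 98.1) in the run labelled WT input D1 and 54.9 CPM (22 counts, 34.4 to 83.1) in KO input D1. It was 127 CPM (62 counts) and 33.5 CPM (140 counts) in the runs labelled WT input RIP8, and 79.4 CPM (36 counts) in KO input RIP8. In the IP runs it was 63.5 CPM (25 counts) and 11.9 CPM (48 counts) for WT IP D1, and 15.8 CPM (62 counts) and 44.5 CPM (116 counts) for KO IP D1. The labels do not say which part of the gene the knockout removes, so counts in this UTR do not test the KO label. The D1 input intervals overlap, and in the edgeR fit Cpeb4 did not pass the threshold in any comparison (log2 fold change 0.48 ± 0.70 SE for KO input against WT input, adjusted p = 0.992). That value turned to −0.0581 without the library labelled WT input RIP8. With the Lars2 UTR taken out of the totals the Cpeb4 levels of the 9 runs run from 12.0 CPM in WT IP D1 batch 3 to 195 CPM in WT input RIP8 batch 1.

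The comparison of the IP over input ratio in WT with that in KO asks which mRNAs need CPEB4 to be precipitated. By edgeR, 0 of 11241 rows passed the threshold, with 120 at an unadjusted p under 0.05, and DESeq2 and limma voom also called 0, with 52 and 228 at an unadjusted p under 0.05. Cpeb4 had a log2 value of 0.10 ± 1.18 (SE), which turned below 0 without factors, without the library labelled WT input RIP8 or KO input RIP8, and with the other run of each library. None of the following genes passed. The smallest p on the higher side belonged to Tmem255a, Snx29 (4.59 ± 1.80), Tmem91, Wnt4, a secreted signalling protein (4.90 ± 2.00), and Vps8 (4.25 ± 1.78). Tmem255a and Tmem91 rest on at most 15 and 10 counts in any library. On the lower side stood Mcf2l, Sar1b, Atic, an enzyme of purine synthesis (−4.20 ± 1.52), the mitotic cyclin gene Ccnb2, and Erh. Mcf2l had 1 count in the library labelled WT IP and 47 in KO IP, with 68 in WT input RIP8 and 0 in the other 3 inputs. Sar1b had 221 counts in WT IP and 586 in KO IP, against 447 in WT input RIP8 and 2 in KO input RIP8. Ccnb2 had 0 counts in both KO inputs, and Erh had 1 count in each. Without the library labelled WT input D1 the same test called 1247 rows, 403 higher and 844 lower. Without WT input RIP8 edgeR called 0 of 8015, with 314 at an unadjusted p under 0.05.

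Gene lists fixed in advance were read in the same comparison. Of 21 lists tested, 6 passed with camera at its preset correlation, all toward lower values: glycolysis (21 of 21 members below 0, adjusted p = 1.15e-05), oxidative phosphorylation (31 of 35, adjusted p = 0.000891), ribosomal proteins (65 of 71, adjusted p = 0.000891), mitosis (24 of 27, adjusted p = 0.0347), DNA replication (22 of 30, adjusted p = 0.0354) and amino acid transport with mTORC1 regulators (17 of 21, adjusted p = 0.0354). With an estimated correlation none passed (adjusted p = 0.915 for each of the 6), and fry gave an adjusted p of 0.907 for each. Without the library labelled WT input RIP8, camera at its preset correlation passed 2 of 18 lists. In the batch 2 runs alone the amino acid transport list turned, with 13 of 20 members above 0 (adjusted p = 0.927 by camera), and mitosis and DNA replication did not pass. Other lists passed by camera only in the batch 2 runs, where each IP group is likewise 1 library. These were CD8 effector genes (13 of 15 below 0), CD8 T cell markers (6 of 7 below 0), histones (14 of 16 above 0) and 3′ UTR regulators (15 of 18 above 0). In the main fit no member of any list passed over all genes or adjusted over the list alone. Among glycolytic genes, Gapdh had a log2 value of −4.36 ± 1.84, Eno1b −4.17 ± 1.97, Eno1 −4.20 ± 2.05 and Pgam1 −3.22 ± 1.60, of which Eno1b turned to 0.22 without WT input RIP8. Gapdh had 3 and 7 counts in the KO inputs. Among respiratory chain genes, Cox8a had −4.46 ± 1.80, while Sdhb and Ndufa7 had 0 counts in the library labelled KO input RIP8 and Uqcrb had 1. The ribosomal protein genes Rps14 and Rpl4 had −3.66 ± 1.75 and −3.92 ± 1.91. In the KO inputs Rps14 had 3 and 1 counts, and Rpl18 had 1 count in each. Among mitotic genes, Aurkb, a chromosomal passenger kinase, had −2.44 ± 1.37, whereas Bub1b and Plk1 had at most 2 counts in either KO input. Of the replication genes, Mcm2 and Mcm4, subunits of the replicative helicase, had −3.08 ± 1.42 and −2.83 ± 1.34, and Mcm7 and Gmnn had at most 2 counts in either KO input. Slc7a5, an amino acid transporter, had −2.35 ± 1.22, Slc7a11 −2.96 ± 1.54, Ddit4 −2.59 ± 1.36 and Mtor −3.13 ± 1.66. In the KO inputs Mtor had 1 and 3 counts and Slc7a11 2 and 5.

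The unfolded protein response list did not pass (23 of 31 members below 0, adjusted p = 0.186). Its smallest p belonged to Atf6b, Creld2 and Asns, each with at most 1 count in either KO input, and Pdia3, a disulfide isomerase of the endoplasmic reticulum (−2.10 ± 1.53), which turned above 0 without WT input RIP8 and with the other run of each library. Nor did the CD8 effector list (12 of 18 below 0, adjusted p = 0.245), in which Gzmb had −4.47 ± 2.02, Ccl5 −2.50 ± 1.26 and Srgn −1.72 ± 1.37, and the perforin gene Prf1 had 1 count in each KO input. In the list of cytoplasmic polyadenylation and deadenylation, 14 of 22 were below 0 (adjusted p = 0.897), with Cnot4 at 2.76 ± 1.30 and Cpsf4 at −1.21 ± 1.19. Sympk and Pabpc4 had at most 1 count in either KO input. Of 33 transcription factors 20 were below 0 (adjusted p = 0.997), with Nfatc2 at −1.44 ± 1.18 and Irf8 at −1.54 ± 1.21, Batf having 1 count in each KO input and Zeb2 11 and 0. Of 14 inhibitory receptors 5 were below 0 (adjusted p = 0.543), with Lag3 at 1.21 ± 1.19, Tigit at 1.37 ± 1.45, Ctla4 at −1.22 ± 1.39 and Entpd1 at −0.93 ± 1.41. Among 3′ UTR regulators 13 of 19 were above 0 (adjusted p = 0.139), and among mRNAs described elsewhere as CPEB targets 11 of 16 were below 0 (adjusted p = 0.145). The activation list gave an adjusted p of 0.800, the immediate early list 0.283 and the histone list 0.897. H2ac24 and H2ac23, histone genes, had −4.46 ± 1.98 and −3.26 ± 1.71, H3c6 had −1.69 ± 1.43, and H3c2 had 3 counts in the library labelled WT IP and 44 in KO IP. The batch 2 runs alone turned the direction of Lag3, Ctla4, Nfatc2 and H3c6, and the other run of each library turned that of Ccl5, Srgn and Irf8. In the batch 2 runs the effector, histone and 3′ UTR regulator lists passed by camera, as given above. Ccl5 also had only 3 and 2 counts in the KO inputs.

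Markers of other cells did not pass either in this comparison. The B cell list had an adjusted p of 0.897, with Cr2 at 3.66 ± 2.00 and H2-Ab1 at −1.89 ± 1.66, and Cd79b and H2-Eb1 had 0 counts in both KO inputs. The CD4 T cell list had 0.997, with Foxp3 at 0.98 ± 1.18 and Zbtb7b at −0.27 ± 1.38, and Il13 had 0 counts in both KO inputs. The NK cell list had 0.791, and its Tyrobp, Klra7 and Klre1 had at most 1 count in either KO input. The myeloid list had 0.800, with Itgam at 2 and 1 counts in the KO inputs, Csf1r at −1.10 ± 1.38, and Cst3 and Xcr1 at no more than 2 counts in either KO input. The CD8 T cell list had 0.336, with Thy1 at −2.52 ± 1.63, Cd3e at −1.58 ± 1.37, Cd8b1 at −1.47 ± 1.34 and Cd3g at −1.21 ± 1.49. The direction of H2-Ab1 and Cd3g turned without WT input RIP8, that of Cd3g, Cd8b1 and Csf1r with the other run of each library, and that of Zbtb7b with limma voom, with the other run of each library and without WT input D1 or KO input RIP8. In the batch 2 runs alone the CD8 T cell list passed by camera, with 6 of 7 members below 0. Of the stromal markers only Pecam1 was tested (−1.32 ± 1.25). Erythroid and platelet markers were too few to test.

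By label, setting WT IP directly against KO IP compares signal with knockout background in RNA prepared alike. Each IP group had 1 library in register. By edgeR 0 rows passed, with 26 at an unadjusted p under 0.05, and DESeq2 and limma voom called 0, with 31 and 192 at an unadjusted p under 0.05. Cpeb4 had a log2 value of −0.37 ± 0.94. None of the following passed. On the higher side in WT IP were Dnase2a, a lysosomal nuclease (2.98 ± 0.97), Frrs1 (2.62 ± 0.92), Lias, which makes lipoic acid (2.48 ± 0.96), Dapk3 (2.76 ± 1.12) and Zcrb1 (2.37 ± 0.99). On the lower side were the tyrosine kinase gene Abl1 (−2.29 ± 0.96), Fez2 (−2.53 ± 1.09), Gpr55 (−2.62 ± 1.14), Car12 (−3.11 ± 1.42), and Gcnt4, with 0 counts in WT IP and 32 in KO IP. With camera, 66 of 71 ribosomal protein genes lay above 0 (adjusted p = 2.37e-10), as did 28 of 35 oxidative phosphorylation genes (adjusted p = 0.0298), whereas 22 of 23 histone genes (adjusted p = 7.06e-06), 17 of 21 glycolytic genes and 17 of 21 amino acid transport genes (adjusted p = 0.0298 for both) lay below 0. In the batch 2 runs alone 4 of these lists turned by camera: 70 of 71 ribosomal protein genes (adjusted p = 1.45e-23) and 29 of 30 oxidative phosphorylation genes (adjusted p = 1.19e-07) lay below 0, and 13 of 16 histone genes (adjusted p = 0.00385) and 12 of 20 amino acid transport genes (adjusted p = 0.787) above. The direction of these 4 lists thus depends on which runs are used, and each IP group is 1 library. With an estimated correlation none of the 5 lists passed (adjusted p = 0.949). The batch 2 runs alone turned the direction of Cpeb4, of Dnase2a, Frrs1, Lias, Dapk3 and Zcrb1, which are all 5 genes named as higher, and of Abl1 and Gpr55. Without the library labelled WT input RIP8, which alters the shared spread, 57 rows passed, 51 higher and 6 lower.

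WT IP against WT input asks what is enriched by the precipitation. By edgeR 0 rows passed, with 828 at an unadjusted p under 0.05, and limma voom called 0, with 1391, while DESeq2 called 42, all higher. Cpeb4 had −1.56 ± 0.89. None of the following passed by edgeR. Higher in the library labelled WT IP were Frrs1 (4.03 ± 0.77), Lias (4.13 ± 0.80), Dapl1 (4.44 ± 0.89), Dnase2a (4.06 ± 0.83) and Lag3, an inhibitory receptor (3.85 ± 0.80). Lower were Gpr55 (−3.72 ± 1.13), Ldb1 (−2.60 ± 0.89), Anln, a cytokinesis protein (−2.91 ± 1.00), Fez2 (−3.05 ± 1.06) and Abl1 (−2.59 ± 0.91). Ribosomal protein genes (70 of 71 above 0, adjusted p = 1.84e-28), oxidative phosphorylation (30 of 35, adjusted p = 4.01e-06) and CD8 effector genes (16 of 18, adjusted p = 0.00732) passed toward higher values with camera, and histones (20 of 23 below 0, adjusted p = 4.90e-05) toward lower ones. All 4 lists turned in the batch 2 runs alone by camera, with 67 of 71 ribosomal protein genes (adjusted p = 1.06e-15), 29 of 30 oxidative phosphorylation genes (adjusted p = 9.17e-07) and 12 of 15 effector genes (adjusted p = 0.0467) below 0 and 13 of 16 histone genes (adjusted p = 0.0576) above. With the Lars2 UTR taken out of the totals, the ribosomal protein genes summed to 4417 CPM in WT IP D1 batch 2 and 82704 CPM in batch 3. With an estimated correlation none of the 4 lists passed by camera (adjusted p = 0.676 for ribosomal proteins, effector genes and histones, and 0.856 for oxidative phosphorylation). Adjusted over the list alone, 3 ribosomal protein genes and 1 inhibitory receptor passed. Without the library labelled WT input D1, 1048 rows passed, 699 higher and 349 lower, without WT input RIP8 2701, 1609 higher and 1092 lower, and with the experiment as a block 577, 530 higher and 47 lower. The batch 2 runs alone turned the direction of Cpeb4, Dapl1 and Dnase2a.

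By label, KO IP against KO input measures the same enrichment without CPEB4, with the same difference in preparation. Both KO IP runs held little in Lars2 (2.23 and 5.40%), and both KO inputs much (50.1 and 37.0%). Ribosomal protein genes also differed between runs of WT IP D1 with unlike Lars2 shares, at 4417 and 82704 CPM without the Lars2 UTR. The shifts below thus cannot be told apart from that split between runs. By edgeR 0 rows passed, with 1749 at an unadjusted p under 0.05, and limma voom called 0, with 1888, while DESeq2 called 200, 124 higher and 76 lower. Cpeb4 had −1.66 ± 0.89. None of the following passed by edgeR. Higher in the library labelled KO IP were Rps14, a ribosomal protein (6.74 ± 1.30), Actn1, an actin crosslinker (4.47 ± 0.92), Gbp2 with 1021 counts against 1 and 2 in the KO inputs, Tspo with 838 against 0 and 1, and Dapl1 with 718 against 1 in each. Rps14 had 4366 counts in KO IP against 3 and 1 in the KO inputs, and Actn1 2410 against 5 and 6. Lower were Pspc1 (−4.95 ± 1.24), Gpr22 (−4.66 ± 1.201), the histone deacetylase gene Hdac2 (−4.46 ± 1.19) and Rspry1 (−4.55 ± 1.22). With camera, 70 of 71 ribosomal protein genes (adjusted p = 2.61e-32), 32 of 35 oxidative phosphorylation genes (adjusted p = 8.08e-11), 19 of 21 glycolytic genes (adjusted p = 0.000258), 17 of 18 effector genes (adjusted p = 0.000804), 22 of 31 unfolded protein response genes and 7 of 7 CD8 T cell markers (adjusted p = 0.0321 for both) lay above 0, and 19 of 23 histone genes lay below (adjusted p = 0.000193). With an estimated correlation none of these 7 lists passed (adjusted p of 0.908 or 0.918). Adjusted over the list alone, 63 ribosomal protein, 23 oxidative phosphorylation, 4 effector, 2 CD8 T cell marker and 2 histone genes passed, with 1 each of the B cell, myeloid, polyadenylation and reported target lists. Without the library labelled WT input D1, 3162 rows passed, 2134 higher and 1028 lower, without WT input RIP8 2767, 1531 higher and 1236 lower, and with the experiment as a block 2129, 1608 higher and 521 lower.

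KO input against WT input compares polyadenylated RNA of the genotypes. By edgeR 0 rows passed, with 616 at an unadjusted p under 0.05, and limma voom called 0, with 472, while DESeq2 called 25, all lower. With the experiment as a block edgeR called 2, all lower. None of the following passed by edgeR. Higher in the libraries labelled KO input were Gpr22 (2.44 ± 0.86), Tmem255a (3.54 ± 1.31), Tmc3 (3.15 ± 1.205), Snx29 (2.94 ± 1.13) and Med27, a Mediator subunit (3.14 ± 1.22). Tmem255a, Tmc3, Snx29 and Med27 rest on at most 16 counts in any input library. Lower were Rps14 (−4.83 ± 1.19), the elongation factor gene Eef1b2, with 3 and 5 counts in the KO inputs against 12 and 1628 in the WT inputs, and Tspo, Ccnb2 and Etfa, which had 1, 0 and 0 counts in KO input RIP8 against 440, 238 and 220 in WT input RIP8. With camera, 69 of 71 ribosomal protein genes (adjusted p = 3.20e-26), 33 of 35 oxidative phosphorylation genes (adjusted p = 2.38e-10), 20 of 21 glycolytic genes (adjusted p = 7.99e-05), 13 of 18 effector genes, 19 of 31 unfolded protein response genes and 21 of 27 mitotic genes (adjusted p = 0.0471 for all 3) lay below 0, and 21 of 23 histone genes above (adjusted p = 2.44e-06). With an estimated correlation none of these 7 lists passed (adjusted p = 0.942). Adjusted over the list alone, 34 ribosomal protein genes and 1 reported target passed. Rps14 had 11 counts in WT input D1 and 1506 in WT input RIP8, against 3 and 1 in the KO inputs. Without WT input D1 2443 rows, 785 higher and 1658 lower, and 8 lists passed, whereas without WT input RIP8 edgeR called 0 of 8015 rows, with 164 at an unadjusted p under 0.05, and camera passed 1 of 18 lists.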

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

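The tests on rows, on names and on the leading row were chosen after the results were seen, except for the thinning to equal depth, whose prediction came first.

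The run labelled KO IP D3 batch 3, which enters no comparison because its rows do not match the row names, held 88.2% of its counts in 1 row, above the 50.1% that was highest in any input run. The runs labelled WT IP RIP8 batch 1 and KO IP RIP8 batch 2, also out of register, held 85.3% and 84.1%.

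The values of the last 11 columns do not belong to the row names beside them. A real difference between libraries is argued against, because rows that share a UTR start should then still hold equal counts, and 0% of them did. Low depth is argued against for 8 of these columns, which hold more counts outside the leading row than the run with the lowest share of such equal rows among the first 9 columns, 35.1%. The other 3, with 54468 to 63844 such counts and 7 to 9 pairs of rows to compare, are too shallow for this test. A candidate explanation is that these columns stand in another row order. The first 9 columns were sorted into falling alphabetical order of gene symbols over all chromosomes. Then 62.5% of 40 windows of 100 rows matched the last 11 columns best within 10 rows of a common offset, −163 rows. That offset was the median of these same windows, whereas the 2.62% by chance is for an offset fixed in advance. In the order of the row names, 2.44% lay within 10 rows of offset 0. The match after sorting may mean that the names and the first columns were sorted by chromosome while the rest was not. Gene-level values were not rebuilt from it.

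Runs named for one library differed more than many runs named for other libraries. Depth is argued against, because after thinning to 50000 counts the median chi-square per degree of freedom of pairs named for one library was still 3.15. A difference between sequencing batches stays open: by name, 19 of 49 thinned pairs from unlike libraries and batches lay below the lowest pair named for one library, but the batch of a run is read from the same names. That the names are set on the values of other runs is a further candidate explanation. The 30 of 84 pairs of other libraries below the lowest pair named for one library are the pattern itself, so they do not test it. A biological cause within one library is not part of the design and was not tested.

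The share of counts in the leading row ran from 1.34 to 88.2% over runs. Preparation as IP or input, as labelled, is argued against as the whole cause, since in 45.8% of 96 pairs the input run was at or above the IP run, although wrong names could hide such a link. The shares above every input run, 84.1, 85.3 and 88.2%, were all in runs labelled IP. Batch is argued against as the whole cause, since within batch 2 the highest share was 37.7 times the lowest, and any 12 of the 20 runs, whatever their names, would give at least 13.1 times. The share went with the total: of the 10 runs with the highest shares, 0 were in the upper part of totals, with at most 619373 counts against at least 2605101 in the others. Libraries with little RNA are a candidate explanation that was not tested. A cause in the library alone would give its 2 runs like shares. By name, WT IP RIP8 held 3.83 and 85.3% and KO IP D3 3.97 and 88.2%, while KO IP D1 was low in both, at 2.23 and 5.40%. As far as the names hold, the unlike pairs argue against a cause in the library alone.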

How the results depend on the processing

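The other run of each library with 2 runs, all 12 libraries as the table stands, the fit without the leading UTR and the lists with each library left out were chosen after the result was seen.

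In the knockout-controlled comparison 0 rows passed under every alternative except leave-one-out, where 0 to 1247 passed, the highest without the library labelled WT input D1. Leave-one-out gave 0 to 57 for WT IP against KO IP, 0 to 2701 for WT IP against WT input, the highest for both without WT input RIP8, and 0 to 3162 for KO IP against KO input and 0 to 2443 for KO input against WT input, the highest without WT input D1. In each such fit a lone library was assumed to vary like the others. DESeq2 called 42 for WT IP against WT input, 200 for KO IP against KO input and 25 for KO input against WT input, and without a filter the same comparisons gave 32, 638 and 116. With the experiment as a replicate block they gave 577, 2129 and 2. Fitted on its own groups alone, KO IP against KO input gave 2646. The other run of each library gave 548 for WT IP against KO IP, 3886 for WT IP against WT input and 1824 for KO IP against KO input. By edgeR with RLE factors, without factors, with the stricter filter, in batch 2 alone, on all 12 libraries as the table stands and without the leading UTR, and by limma voom, 0 rows passed in all 5 comparisons. At an unadjusted p under 0.05 all 12 libraries gave 3, 0, 1, 6 and 2 rows of 16036, the batch 2 runs 1290, 604, 81, 1161 and 236 of 7990.

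With an estimated correlation and with fry, 0 gene lists passed in each of the 5 comparisons, against 6, 5, 4, 7 and 7 with the preset one. The block left 2 lists for WT IP against KO IP, and for KO input against WT input no factors left 4 and batch 2 alone left 4. These counts hide turned lists: in batch 2 alone 1 passing list turned in the knockout-controlled comparison, 4 of 5 did for WT IP against KO IP and 4 of 4 for WT IP against WT input. Leave-one-out left 2 to 7, 4 to 5, 4 to 6, 6 to 8 and 1 to 8 lists in the 5 comparisons.

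Of 1681 values of named genes under alternatives, 50 turned their direction. In the batch 2 runs these were, in the knockout-controlled comparison, Lag3 at −2.84, Ctla4 at 0.37, Nfatc2 at 0.61 and H3c6 at 1.74. For WT IP against KO IP they were Cpeb4 at 2.80, Dnase2a at −2.07, Frrs1 at −1.18, Lias at −1.74, Dapk3 at −1.46, Zcrb1 at −2.32, Abl1 at 0.61 and Gpr55 at 0.94, and for WT IP against WT input Cpeb4 at 0.71, Dapl1 at −1.03 and Dnase2a at −0.62. All further ones were in the knockout-controlled comparison, save Cpeb4 in KO input against WT input. With limma voom they were Zbtb7b at 0.0842 and Klra7 at 0.22, without factors Cpeb4 at −0.40 and Klre1 at −0.61, and without a filter Klre1 at −0.0596. With the other run of each library they were Cpeb4 at −1.91, Asns at 0.35, Pdia3 at 0.93, Ccl5 at 0.17, Srgn at 1.01, Irf8 at 0.0818, Rpl18 at 0.99, Zbtb7b at 0.70, Cd8b1 at 0.60, Cd3g at 1.53, Cst3 at 1.203 and Csf1r at 0.25, and Cpeb4 in the inputs at −0.46. Leave-one-out ranges that cross 0 were −2.02 to 1.26 for Cd3g, −0.30 to 0.68 for Cpeb4, −5.12 to 0.22 for Eno1b, −3.08 to 1.498 for H2-Ab1, −5.64 to 0.79 for Klra7, −5.14 to 0.94 for Klre1, −10.48 to 0.19 for Ndufa7, −2.91 to 0.37 for Pdia3, −4.64 to 0.0589 for Rpl18, −4.06 to 2.35 for Tyrobp, −3.74 to 4.86 for Xcr1, −1.35 to 0.67 for Zbtb7b, −5.91 to 6.34 for Zeb2, and −0.0581 to 1.05 for Cpeb4 in the inputs.

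A block by experiment and genotype and fits or lists without the whole of experiment D1 or RIP8 were not run, because no residual degrees of freedom or no contrast is left. WT IP against KO IP could not be fitted on its own groups, with 1 library each in register, and the motif test and its alternatives were not run for lack of a genome sequence. Experiment D3 has no column in register.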

Other observations

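The values of this part were chosen after the data had been seen, and none was tested.

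With the Lars2 UTR taken out of the totals, since it holds between 1.16 and 50.1% of them, gene groups differed in level between the 9 runs in register to unlike degrees. The 74 named ribosomal protein genes summed to between 3310 CPM in the run labelled KO input RIP8 and 82704 CPM in WT IP D1 batch 3, and the 35 nuclear respiratory chain genes to between 505 and 4916 CPM. Glycolytic genes summed to between 4154 CPM in KO input D1 and 26972 CPM in WT input RIP8 batch 2. These groups were split by the Lars2 share without overlap. In the runs with 34.8% or more in Lars2 they summed to at most 4417, 681 and 7946 CPM, in the order given. In the other runs, with 5.40% or less, they summed to at least 26279, 3986 and 14320 CPM. The runs labelled WT IP D1 fell on opposite sides, as did those labelled WT input RIP8. On the same scale, 20 RNA-binding regulators of 3′ UTRs summed to between 3547 and 7618 CPM, 33 T cell transcription factors to between 8610 and 11565 CPM and 31 unfolded protein response genes to between 3989 and 4789 CPM. The regulators were split the other way, with 6338 CPM or more in the high-share runs and 4404 CPM or less in the others. The transcription factors and unfolded protein response genes overlapped. Edem1, which takes part in degradation of misfolded proteins, had 1400 CPM in the run labelled WT input D1 and 263 CPM in KO IP D1 batch 2, whereas Pdia3, an abundant chaperone of the same compartment, had 36.4 and 529 CPM.

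Of the CPEB family, Cpeb2 had 6 to 55 counts in the 9 runs and Cpeb4 22 to 140, while Cpeb3 had at most 5 and Cpeb1 at most 2. Pan3, a deadenylase subunit, had 926 CPM in the run labelled WT input RIP8 batch 1 and 49.6 CPM in WT IP D1 batch 3 on that scale. After the Lars2 UTR, the most counted named UTR was that of Samhd1 in the runs labelled WT input D1, KO input D1 and WT IP D1 batch 2, and that of Phc3 in WT input RIP8 batch 1 and KO input RIP8 batch 2. In WT IP D1 batch 3, Wdr89 was ahead of Lars2, with 53981 counts, and Actb followed Lars2 in KO IP D1 batches 2 and 3 and in WT input RIP8 batch 2.

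Olfactory receptor genes, which T cells are not known to use, had no count in the first 9 columns for 185 of 192 named rows, against 41 of 192 in the last 11 columns under the same row names. Ribosomal protein rows without a count numbered 1 of 81 in the first 9 columns and 26 of 81 in the last 11.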
